A study of Homo sapiens with 7 samples.

How the data were processed

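The series holds 7 two-channel spotted arrays of LNCaP, an established human prostate cancer cell line. Per the labels, cultures were kept for 10 h with or without emetine at 100 µg/ml. Emetine is a drug that blocks translation. On 6 arrays actinomycin D, which blocks transcription, was then added at 5 µg/ml to both cultures. Harvests followed at 0, 10 and 30 min and at 1, 2 and 4 h, with 1 array per time. The remaining array, called the self-self array here, carries emetine-treated RNA in both channels, was harvested at 0 min, and its label mentions no actinomycin D. Per the labels, 4 µg of mRNA went into each channel, untreated RNA was labelled with Cy5 and emetine-treated RNA with Cy3. No dye swap is labelled. For the 0 min emetine array the labels disagree: the description speaks of emetine-treated RNA in both channels, and the source of channel 2 is untreated cells. It was kept in the group its title and channel sources give. Across probes its log2 ratios correlated at 0.7706 (2 h) to 0.9055 (10 min) with the other emetine arrays, and at 0.3571 with the self-self array (Pearson's r).

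The deposited values are log2 ratios. Per the labels, background was subtracted, the average intensity of the tumour sample was divided by that of the reference at each spot, and the authors normalized each slide on housekeeping genes by ratio statistics. A quality filter at 0.5 is also described, yet each array lists a value for all 15488 probes. The base of the logarithm was read from the values. Base 2 turned 100% of the negative values into whole ten-thousandths, within 0.05 of a step, on each array. Scanner and software are not given in the sources used here. The labels do not say which channel was the numerator, so the sign is that of the deposited ratio and no direction between emetine-treated and untreated cells is stated. The arrays were not centred: the medians of measured probes were 0.16 on the self-self array and, in time order, 0.04, 0.03, 0.02, 0.02, 0.02 and 0.05 on the emetine arrays. The number of arrays limits the precision. Brightness and background of single spots were not analysed here.

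On each array between 302 and 491 probes shared 1 value, while the next most common value was held by at most 9 probes. That shared value was taken as a placeholder and treated as not measured. This choice was made after seeing the values, and the fit was repeated with the shared values kept.

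The platform annotation supplied with the series pairs 11966 probes with 1 gene symbol, 464 with several and 3058 with none. Of the probes with 1 symbol, 11936 matched a gene identifier in the RefSeq gene table of GRCh38.p14. Before any name was used, probes given the same symbol were compared. Over 2123 such pairs the Pearson correlation of the mean log2 ratio was 0.0093, and a two-sided permutation test with 100000 shuffles gave p = 0.669. The match through the deposited identifier was therefore not borne out by the values. For that reason no gene is named here, each probe was analysed on its own, and at most 2 probe identifiers are printed in each direction. The design fixed before the data were examined had averaged the probes of a gene. That average, by deposited identifier, was kept as an alternative chosen after seeing the data. Of the fixed rule for named genes, the part used here takes the highest and lowest mean ratios among probes past the test with the same sign on every array measured.

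Log2 ratios of the 6 emetine arrays were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intercept and time in hours, centred. The intercept gives the mean log2 ratio and the slope its change per hour. Probes measured on at least 5 of the 6 arrays entered, which left 14940 probes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the mean also had to be at least 2-fold from 1. No time point was replicated, so the p-values measure the scatter of 6 single arrays about a line, with 4 residual degrees of freedom, and this scatter may be technical. Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 5 genes measured on all 6 arrays. Their members could be looked up only through the deposited identifier. Of 21 lists fixed before the data were examined, 20 were large enough. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

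The fit was tested on simulated data with 200 changed probes and the moderated variances of the 14940 real probes. Moderated variances are more alike between probes than the probes' own scatter, which favours the fit. The fit recovered 100% of mean shifts of 1.5 on the log2 scale, with 1 false call. With a median standard error of 0.09 for the mean, that recovery was to be foreseen. For slopes it recovered 0% at 0.2 per hour, 89% at 0.4 per hour and 99.5% at 0.8 per hour, with 0, 9 and 21 false calls. Slopes of 0.2 per hour were out of reach. The simulated noise was independent between probes and arrays, with unchanged probes centred on 0. A bias of the spot or dye that recurs across arrays was not simulated. The false calls therefore do not tell how many real calls reflect such a bias.

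The alternatives tried were centring each array, other minimums of measured arrays, robust moderation, leaving out each array, subtracting the self-self array, other size limits, other time scales and, for lists, an estimated correlation and ranks. Each probe on its own, also planned as an alternative, became the main fit of the probes. Alternatives chosen after seeing the data were keeping the shared values, averaging by identifier, setting each block of consecutive rows to the array median and scaling each array to the same spread, by the median absolute deviation or by the SD.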

Results

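Ratios between emetine-treated and untreated LNCaP cells were followed for 4 h after transcription was blocked. The design asks which transcripts differ between the cultures and whether the ratio moves as RNA decays. The data were 6 emetine arrays, 1 each at 0, 10 and 30 min and at 1, 2 and 4 h, and 1 self-self array. Of 15488 listed probes, between 14997 and 15186 had a value on each emetine array and 15013 on the self-self array. There were no replicates of any time point. Above and below refer to the deposited ratio, whose numerator the labels do not state. Probes are not named by gene, because probes that the annotation gives 1 symbol did not vary together (Pearson's r across 2123 probe pairs = 0.0093, two-sided permutation p = 0.669).

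On single arrays, many probes lay at least 2-fold from a ratio of 1. At 0 min 1195 probes were above and 1140 below, which together were 15.5% of those measured. The share was 17.5% at 10 min, 17.0% at 30 min, 19.4% at 1 h, 14.6% at 2 h and 24.2% at 4 h. On the self-self array it was 10.8%, with 1555 probes above and 71 below. Probes below 1 by at least 2-fold were therefore 0.473% of the self-self array, and between 5.18% (2 h) and 11.9% (4 h) of the emetine arrays. Probes above by that much were 10.4% of the self-self array, and between 7.92% (0 min) and 12.2% (4 h) of the emetine arrays, so as deposited the upper share of the self-self array lay within the range of the emetine arrays. It did not once each array was centred on its median, where 983 probes were above on the self-self array and between 1115 and 1720 on the emetine arrays. Below, the centred counts were 131 on the self-self array and between 832 (2 h) and 1910 (4 h) on the emetine arrays. At 3-fold, 317 probes were above on the self-self array and between 381 and 868 on the emetine arrays. These are counts on single arrays and carry no test.

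**Figure D1:**
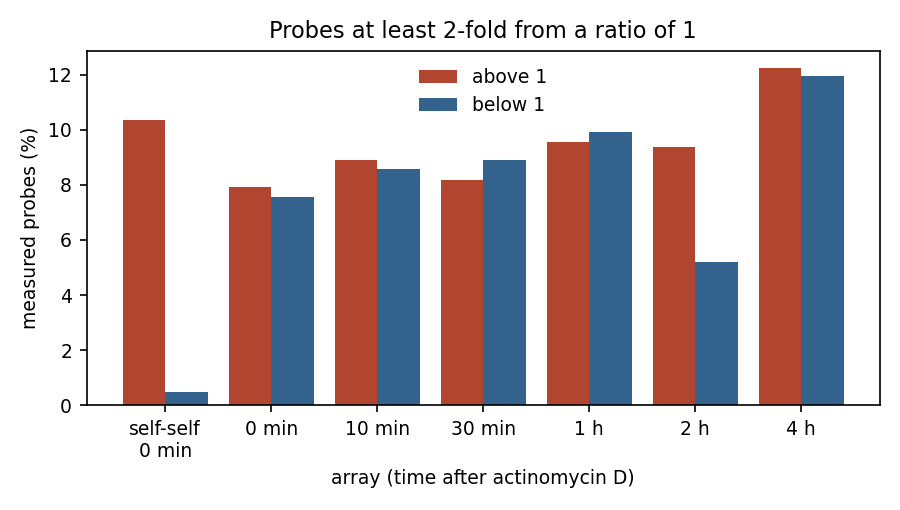
Bars give the percentage of measured probes at least 2-fold above or below a deposited ratio of 1 on each of the 7 arrays, 1 array per time. The self-self array has 10.4% above and 0.473% below, and the 4 h array has 12.2% above and 11.9% below.

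The 2 h array had the fewest low ratios of the emetine arrays. It had 1423 probes at least 2-fold above and 787 below, whereas the 1 h array had 1441 above and 1495 below. Across probes, the Pearson correlation of the 2 h array with the other emetine arrays lay between 0.767 (4 h) and 0.828 (1 h), and that of the 4 h array between 0.767 (2 h) and 0.834 (30 min). The highest correlation between emetine arrays was 0.922, for 10 and 30 min. Correlations of the emetine arrays with the self-self array ran from 0.172 (2 h) to 0.390 (1 h). Probes are not independent replicates.

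Over the time course, the mean ratio was at least 2-fold from 1 past the limma test at 2331 of 14940 probes. Of these 1210 (8.10%) were above and 1121 (7.50%) below. By the adjusted p alone 5444 probes were above and 4747 below, so the 2-fold minimum did most of the selecting. The sign was the same on every emetine array measured for 1199 of the probes above and 1112 of those below. Large ratios were more frequent above. At least 4-fold were 234 probes above and 110 below, and at least 8-fold were 43 above and 4 below. With each array centred on its median, the split at 2-fold turned to 1143 above and 1179 below. The median standard error of the mean log2 ratio was 0.09.

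The highest mean was at probe 13216, at 5.12 ± 0.29 on the log2 scale (SE, n = 6 arrays, limma adjusted p = 4.52e-07), a 34.7-fold ratio. Its log2 ratio was 3.21 at 0 min, 6.13 at 1 h and 5.80 at 4 h, and -0.49 on the self-self array. Probe 11250 followed at 5.09 ± 0.17 (SE, n = 6 arrays, limma adjusted p = 5.90e-08). It stood at 4.57 at 0 min and 5.54 at 4 h, and at -0.11 on the self-self array. The lowest mean was at probe 13682, at -3.44 ± 0.12 (SE, n = 6 arrays, limma adjusted p = 6.12e-08), with -3.64 at 0 min and -2.82 at 4 h, and -0.54 on the self-self array. Probe 12581 had a mean of -3.38 ± 0.50 (SE, n = 5 arrays, limma adjusted p = 0.000368). Its single value at 1 h was -6.08, it was measured at -2.45 at 0 min, and it read 0.97 on the self-self array.

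The probes with a low mean ratio also lay low on the self-self array. Their median there was -0.49, against 0.16 for all tested probes and 0.01 for the probes with a high mean ratio. Probes with a slope past the test, described next, also had medians below that of all tested probes. Subtracting the self-self log2 ratio moved the split to 1093 above and 1548 below, or 41.4% above in place of 51.9%. Of the 2331 probes, 1320 were among those then past the test. The self-self array was subtracted without centring, so its median of 0.16 lowered the ratios as a whole. How much of the new split comes from this offset was not tested. The same values were taken from every emetine array, so their error does not enter the scatter behind the p-values.

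The ratio moved with time past the limma test at 273 probes, of which 239 rose and 34 fell. At an unadjusted p under 0.05 there were 1566 rising and 915 falling slopes, where 747 in all would be called by chance. Among the rising probes the median slope was 0.38 per hour on the log2 scale and the largest 0.85. Their median log2 ratio was 0.23 at 0 min, 0.68 at 1 h, 1.05 at 2 h and 1.73 at 4 h. Among the falling probes the median slope was -0.40 per hour, and the median log2 ratio was -0.16 at 0 min, -0.62 at 2 h and -2.10 at 4 h. Of the rising probes, 95 also had a mean ratio at least 2-fold above 1 past the test, where 19.4 would overlap if both lists were independent, and 3 had one below. The 2 lists come from the same arrays and share 1 error estimate per probe. A probe that rises from a ratio near 1 also has a mean above 1, as 188 of the 239 had. An excess over 19.4 is therefore partly built in. Of the falling probes, 13 had a mean at least 2-fold below and 0 had one above. The smallest adjusted p was 0.00452. On the self-self array the median was -0.27 for the rising and -0.38 for the falling probes, against 0.16 for all tested probes. A median below that of all probes there was thus shared by the groups called by mean and by slope.

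The count of slopes depended on which arrays were fitted. With time in hours, the 4 h array lies farthest from the mean time and weighs most on a slope. The median of the falling probes was -0.45 at 1 h and -0.62 at 2 h, then -2.10 at 4 h. Without the 0, 10 or 30 min array the count was 39, 30 or 36, without the 1 h array 134, and without the 2 h array 649. Leaving out 1 array also lowers the 4 residual degrees of freedom. A lower count therefore does not by itself show that the slopes rest on that array. Without the 4 h array 204 probes passed, of which 59 were among the 273. With late times (1, 2 and 4 h) set against early ones it was 5.

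**Figure D2:**
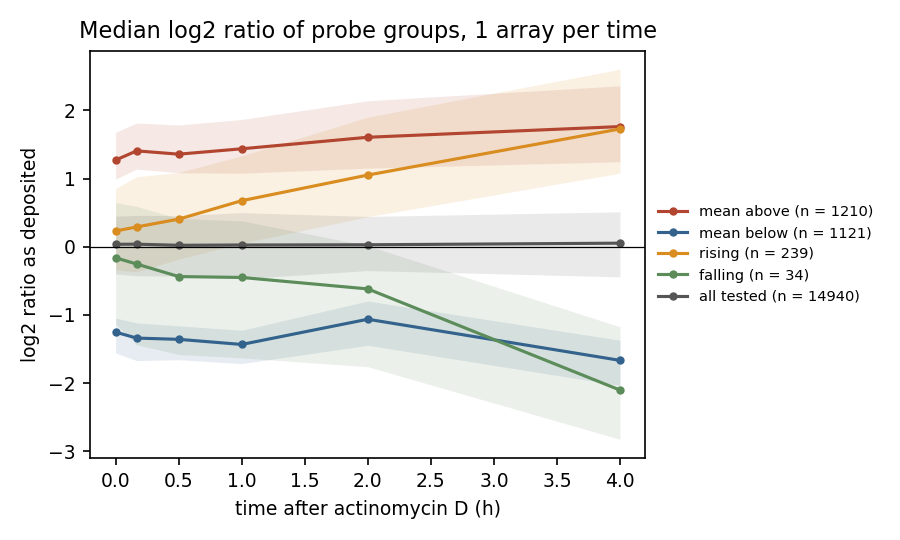
Lines give the median deposited log2 ratio of probe groups against time after actinomycin D in hours, and shading their quartiles, with 1 array per time. The 239 rising probes go from 0.23 at 0 min to 1.73 at 4 h, and the 34 falling probes from -0.16 to -2.10; the groups were chosen on these arrays.

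Gene lists were looked up through the deposited identifier, which the same-symbol pairs did not bear out. None of the 20 lists passed, whether for the mean ratio (smallest camera adjusted p = 0.758) or for the trend (smallest camera adjusted p = 0.993). With an estimated correlation the smallest adjusted p was 0.909 for the mean and 0.994 for the trend. At an unadjusted p under 0.05 there were 0 lists in both. Summed over lists, which overlap, 121 of 841 members passed the test of the mean ratio over all genes, a share of 14.4%, equal to the 14.4% of all genes and unnamed probes so tested. Adjusted over the list alone, the number was also 121. For the trend 9 members passed over all genes, a share of 1.07% against 1.20% of all genes and unnamed probes so tested. With the adjustment over the list alone it was 31. Markers of other cell types were 1 of these lists. Because the members cannot be placed with confidence, these counts do not speak for or against any gene group.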

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

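All tests of explanations in this part were chosen after the slopes had been seen. Time points under the same contrast differed by the trend test at 239 probes that rose and 34 that fell. Across 100 orders of the 6 times, the real one included, 1 order gave as many probes past the test, namely the real order with 273. The highest of the others gave 252, and its order was close to the real one (rank correlation 0.943). The next highest gave 11, and the median of the others was 0. Only 16 of the 100 orders, the real one among them, kept the 4 h array last. Orders that moved it gave at most 8, so few of the orders varied only the times before 4 h. A wider spread of all ratios on late arrays was tested as another explanation. The spread did not grow steadily: the SD of measured log2 ratios was 0.75 at 0 min, 0.85 at 1 h, 0.81 at 2 h and 0.97 at 4 h, and the scaled median absolute deviation was 0.63, 0.72, 0.59 and 0.71. With each array scaled to the same deviation 69 probes passed, of which 68 were among the 273, and with each array scaled to the same SD 42 passed. The slopes themselves were mostly kept. The median slope of the rising probes was 0.38 per hour before (median SE 0.06), 0.35 after scaling by the deviation (median SE 0.07) and 0.31 after scaling by the SD (median SE 0.06). Over both directions and both scalings, the lowest of the lower quartiles of the share of the slope kept was 0.685. The arrays differed too little in spread for scaling to take away most of a steep slope, and these probes were chosen for their slopes. The share kept is therefore a weak test. It argues only against a stretch of all ratios in proportion as the whole cause of these slopes. The number past the threshold depends on the scaling, so a part played by the spread stays open. A difference in decay between the cultures stays open and untested, as do differences between single arrays, since each time has 1 array.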

How the results depend on the processing

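The count of mean ratios lay within 1.5 times of 2331 under 18 of 20 alternatives. Planned as 1 of the 20 was the fit of each probe on its own. That is the main fit here, so its match was fixed beforehand. The count was 5260 at 1.5-fold and 10191 with no minimum of size. The adjusted p alone thus passed most of the 14940 probes tested, and the 2-fold minimum did most of the selecting. A small offset that recurs on every array would pass the adjusted p too. The count of slopes, 273, moved by more under 11 of 20, which again include that fit of each probe on its own. Subtracting the self-self array takes the same value from every emetine array of a probe, so no slope could change. Its count of 286 differed only through the set of probes tested, here 14877. When 1 array was left out, the count of slopes ran from 30 (without the 10 min array) to 649 (without the 2 h array). The count was 133 on ranks of time and 5 for late against early times. Under alternatives chosen after seeing the data the count of slopes was 162 with the shared values kept and 151 averaged by identifier, where fewer units were tested. With equal spreads (MAD) it was 69 and with equal SDs 42. The cause of these moves was not tested. Rising slopes outnumbered falling ones in each of these fits. Probes at least 1.5-fold from 1 numbered 4854 on the self-self array and, in time order, 5584, 5856, 5853, 6394, 5088 and 6444 on the emetine arrays. At least 3-fold they numbered 347 on the self-self array and 669, 831, 811, 987, 888 and 1585. For lists by identifier, 1 list (apoptosis regulators, camera adjusted p = 0.0253) passed for the mean ratio with the self-self array subtracted, and 0 under the other 10 alternatives. Since the identifier was not borne out, that pass does not speak for or against this gene group. For the trend 0 passed under all 11. Each ratio sets the 2 channels of 1 array against each other, so the pairing is only between the channels of an array. No dye swap is labelled, so the mean over the emetine arrays cannot by itself separate treatment from a constant dye or spot offset. The arrays are successive harvests, so the p-values of the mean do not rest on replicates of a time point. No time point had a second array. Signal over background was not analysed, so its limit on dim spots is unknown.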

Other observations

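Of the tests in this part, only that of the direction of the ratio was written before the data were examined. A translation block is known to keep immediate early messenger RNAs high, so a high median of that list was to be read as a sign that the ratio is emetine over untreated. By deposited identifier the list's median was above that of all named genes on 0 of the 6 emetine arrays, by small margins: -0.03 against 0.04 at 0 min and -0.06 against 0.05 at 4 h. That would have spoken for the opposite direction, but the test presumes that the identifier gives the right gene, which the correlation of 0.0093 between same-symbol probes does not bear out. Looked up instead through the layout by place described next, the same list was above on 6 of the 6 emetine arrays. That lookup was made after seeing the data and rests on an unproven layout, so the direction of the ratio stays open.

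Probes with 1 symbol did not vary together by identifier, and a candidate explanation is that the rows follow the place of a spot on the printed array. The rows fall into 32 blocks of 484, a grid of 22 by 22 spots. When the annotation was laid along the blocks, same-symbol pairs outside the repeated control spots correlated at 0.416 over 1934 pairs (permutation p = 1e-05, the smallest that 100000 shuffles can give). The largest size of r in those shuffles was 0.102, and at 80 other offsets within the block 0.055. On the self-self array the correlation was 0.345. Over the emetine arrays it was above 0 in all 32 blocks, from 0.118 to 0.685, and in 33 of 34 plates, the exception being at -0.014. This layout was found by searching many reorderings of the same values, so it is a hypothesis, and it places 13824 of the 15488 rows. No gene is named from it here.

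Mean ratios far from 1 could reflect a bias of the spot or dye that the self-self array would show too. For the probes at least 2-fold above, the median share of the mean log2 ratio that the self-self array showed was 0.0047 and the upper quartile 0.403. For those below, the median share was 0.342 and the upper quartile 0.452. With the self-self array and the means taken relative to their medians, the median share was -0.091 above and 0.443 below, and the upper quartile 0.288 above and 0.563 below. Of the probes above, 217 of 1207 (18.0%) were at least 2-fold above on the self-self array too, against 10.3% of all tested probes. Of those below, 12 of 1108 (1.08%) were at least 2-fold below there, against 0.155% of all tested probes. Such a bias stays open for both groups, since these shares rest on 1 self-self array and, for the probes below, depend on the centring. No biological explanation was tested, since the direction of the ratio is not settled.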
